A study of Bos taurus with 44 samples.

How the data were processed

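Each of the 44 arrays held RNA of cattle in 2 colours, 1 sample labelled with Cy3 and the other with Cy5. Per the labels' protocols, total RNA of frozen tissue was isolated with Trizol, purified on columns, copied into cDNA from oligo-dT primers and coupled to the dyes. The labels name the area of the tissue (caruncular or intercaruncular) and, for each dye, a group and an animal or a pool. In cattle, caruncles are the parts of the uterine lining where the placenta attaches, and intercaruncular tissue lies between them. The groups are artificial insemination (AI), in vitro fertilisation with embryo transfer (IVF-ET), somatic cell nuclear transfer (SCNT) and CJ, which the labels describe by the word cycle. The AI animals of the IVF-ET arrays carry another name in the labels (IAT) than those of the SCNT part (IAJ), and no animal is in both.

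The values deposited by the authors are log2 ratios of the 2 dyes, 1 per spot and array. Their base was tested on the 331 values below -4, of which 100.0% equalled log2 of a ratio with 4 decimals (tolerance 6e-05), against 0.9% for the natural logarithm and 0.0% for base 10. Spot intensities were not analysed here, and the background correction and normalization are not given in the sources used here. Array medians lay between -0.0164 and 0.0124, and no further normalization was applied. The labels do not state which dye is the numerator. Cy5 over Cy3 was taken as likely, because interferon-stimulated genes then lie higher and OXTR lower in AI and SCNT than in CJ animals, the direction known for early pregnancy in ruminants.

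The 27648 rows hold 13824 probes with 2 spots each, which were averaged. The supplied annotation pairs 8645 probes with 1 gene symbol, 105 with several and 5074 with none. Through the Entrez number, the supplied gene table gave the same symbol for 8620 of them, and the other 25, whose number it does not hold, kept theirs; the named probes cover 8073 different symbols. Control spots are not marked in the sources used here and stayed in. Where a gene has several probes, the probe with the fewest missing values stands for it, and the text says where another probe differs. A total of 52 probes lacked a value on at least 1 array, and probes with a value on at least 80% of the arrays of a fit were tested. The SD of the log2 ratios of an array was 0.221 to 0.62 (median 0.422), and the 2 spots of a probe correlated with r of 0.545 to 0.935 (median 0.794, across probes, which are not independent replicates).

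The animal was the replicate. IVF-ET was compared with AI on 10 arrays per area, a closed loop in which 5 IVF-ET and 5 AI animals were each hybridised once in each dye, and all 5 IVF-ET and 3 of the AI animals are in both loops. A fit over both loops tested the difference between the areas, taking the 2 areas of an animal as separate. An alternative linked them by a block per animal. SCNT and AI met directly only in the caruncular area, on 4 arrays of 2 pairs of pools with swapped dyes; each pair was averaged, and its 2 values were tested against 0. The labels do not say how many animals a pool holds. In the intercaruncular area, 10 arrays set SCNT against CJ and 10 set AI against CJ, and 1 fit over these 20 arrays (5 SCNT, 4 AI and 5 CJ animals) gave all 3 differences. AI animal 3 of that part is named on 4 arrays, 2 of them with the same CJ animal in both dyes. AI animals were numbered anew in each fit, so AI animal 3 is a different animal in each loop and in the fit with CJ. Of the AI animals in both loops, caruncular animals 1, 2 and 5 are intercaruncular animals 2, 4 and 5. The IVF-ET animals have the same numbers in both loops.

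Each probe was fitted with limma 3.58.1 in R 4.3.3 by generalised least squares with a dye term and 1 correlation for arrays that share an animal. That correlation was 0.13 in the caruncular loop, 0 in the intercaruncular loop, 0.01 over both and 0.12 in the fit with CJ. Moderated statistics were adjusted by the Benjamini-Hochberg method over all probes tested, with 0.05 as the threshold. Errors are standard errors (SE) of the fit. The design, the named genes, the gene lists and most alternatives were fixed before the data were examined. Genes were named by rule: per comparison, up to 12 largest rises and falls past the threshold with 1 symbol and the same sign on at least 80% of the arrays (no sign rule where SCNT and AI meet only through CJ), the 4 members with the smallest p of each list past its threshold or with at least 3 members past it, the same names side by side across comparisons, and ISG15, MX1, MX2, OAS1, PGR, ESR1, OXTR, PTGS2 and SERPINA14 wherever measured.

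Of 32 gene lists, 29 with at least 5 measured genes were tested with camera at its preset correlation of 0.01, using 1 probe per gene. Neutrophil, red blood cell and adipocyte markers had 4, 3 and 3 measured genes and were not tested. Camera asks whether a list moved against the other genes. Camera with an estimated correlation and fry, which asks whether the genes of a list move one way on balance, were alternatives. The list of cytosolic ribosomal proteins was made from a symbol pattern that also takes RPS6K kinases, RPL7L1, RPS19BP1 and RPS27L.

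Other alternatives were arrays taken as independent, no dye term, the 4 arrays of pools taken separately, robust moderation, other limits on missing values, median centring, a common median absolute deviation, the mean of a gene's probes, a threshold of 0.01, AI animal 3 taken as 2 animals, and each animal left out in turn, for the difference between the areas also in both areas at once. Leaving out an animal drops all of its arrays, so calls can also be lost through lower precision. For comparisons that share CJ animals, 20 simulated data sets without any effect gave the agreement that sharing alone brings. In 20 splits of the CJ animals, the 2 comparisons shared no CJ animal. For each fit with animals, 100 of the possible splits of the animals were drawn, for the difference between the areas once with each area on its own and once with each animal moved in both areas.

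The fits were tested on simulated data with the real layout of arrays, 13824 probes (13816 in the intercaruncular loop) and 200 changed probes. Errors were drawn as normal and independent between probes, with the variances and correlation that the real fits estimated. The rates hold for such data and may be lower in the real data. Changes of 1 on the log2 scale were called for 98.5% of changed probes in both loops, 95.5% for the difference between areas, 98.5% for AI against CJ and 92.5% for the 3 comparisons with SCNT. Changes of 0.5 were called for 88.1% in the caruncular loop, 49.3% in the intercaruncular loop, 46.3% between areas, 76.1% for SCNT and 56.7% for AI against CJ, 38.8% for SCNT against AI in the intercaruncular area and 20.9% in the caruncular area. Summaries and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.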

Results

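Gene expression was measured in caruncular and intercaruncular tissue of cattle after artificial insemination (AI), in vitro fertilisation with embryo transfer (IVF-ET) or somatic cell nuclear transfer (SCNT, cloning from a body cell), and in CJ animals. The labels describe CJ by the word cycle. The 44 arrays each set 2 RNA samples against each other on 13824 probes, of which 8645 name 1 gene. IVF-ET and AI were compared on 10 arrays per area, with 5 animals per group. SCNT and AI were compared on 4 arrays of pooled caruncular RNA, 2 pools per group. In the intercaruncular area, 5 SCNT and 4 AI animals were each set against CJ animals (5 animals) on 10 arrays per group. The values are log2 ratios of the 2 dyes, and the number of animals or pools limits the precision of the differences.

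The intercaruncular arrays with CJ asked how tissue of SCNT and AI animals differed from that of CJ animals. In SCNT animals, interferon-stimulated genes rose and the oxytocin receptor and the main fibrillar collagens fell. RSAD2, an antiviral enzyme induced by interferon, rose by 5.44 ± 0.66 on the log2 scale (SE, 5 SCNT and 5 CJ animals, limma adjusted p = 5.11e-06, higher on 10 of 10 arrays), which is 43.5-fold. ISG15, a ubiquitin-like protein induced by interferon, rose 25.1-fold (4.65 ± 0.60, adjusted p = 9.79e-06), and OXTR, the oxytocin receptor, fell 11.6-fold (-3.54 ± 0.32, adjusted p = 1.74e-07). These signs read each ratio as Cy5 over Cy3, which the labels do not state. That reading is likely because it puts interferon-stimulated genes higher and OXTR lower than in CJ animals, as known for early pregnancy in ruminants. The direction of these genes against CJ is therefore no finding of its own. Under the other reading every sign in the text turns.

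Among the other large rises in SCNT against CJ animals were FABP3, a fatty acid-binding protein (4.28 ± 0.41, adjusted p = 3.96e-07), PLET1, a surface protein of placental and epithelial progenitor cells (4.06 ± 0.38, adjusted p = 2.52e-07), LY6G6C, a small surface protein (3.62 ± 0.27, adjusted p = 1.17e-08), and DKK1, a secreted Wnt inhibitor (3.03 ± 0.51, adjusted p = 0.000163). SLC2A1, a glucose transporter, rose by 2.58 ± 0.24 and HPGD, which breaks down prostaglandins, by 2.64 ± 0.61. The fall with the smallest adjusted p was that of SNAI2, a transcription factor of mesenchymal cells (-2.97 ± 0.15, adjusted p = 3.14e-11). GADD45G, a growth arrest gene (-2.86), NPY, a neuropeptide (-2.42), and the progesterone receptor PGR (-1.17 ± 0.12, adjusted p = 9.15e-07) fell too. In all, 1436 probes were higher and 1558 lower in SCNT than in CJ animals (21.7% of those tested, 982 and 1247 named genes), and 378 of them differed by more than 1 on the log2 scale. PTGS2 (-0.04 ± 0.12, its other probe the other way at 0.89, adjusted p = 0.13), ESR1 (-0.31 ± 0.15) and SERPINA14 (0.15 ± 0.80) did not pass the test.

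Of the 33 measured interferon-stimulated genes, 29 rose and 0 fell in SCNT against CJ animals (29 and 1 adjusted over the list alone), with a median of 1.32 (camera adjusted p = 2.58e-18, adjusted p = 0.121 with an estimated correlation). Complement genes rose, 7 of 16 with 1 fall (10 and 2 adjusted over the list alone). Among them were C1S (2.26), SERPING1 (1.99) and C1QB (1.44), and this call held with an estimated correlation (adjusted p = 0.0324). So did that of epithelial markers, of which 6 of 11 rose and 1 fell (7 and 1 adjusted over the list alone), led by the tight-junction gene CLDN3 (1.29 ± 0.17, adjusted p = 0.0324 for the list with an estimated correlation). MHC class I presentation had 7 rises of 14 (9 adjusted over the list alone), with B2M at 2.23 and BOLA-NC1 at 1.79 (1 of 2 other probes of BOLA-NC1 differed). Its 2 falls, under both adjustments, were the endoplasmic reticulum chaperones PDIA3 (-0.82) and CALR (-0.66). Its adjusted p was 0.16 with an estimated correlation. MHC class II presentation had 3 rises of 8 (5 adjusted over the list alone), among them BOLA-DRA at 0.77, and an adjusted p of 0.121 with an estimated correlation. Trophoblast markers, genes of the outer cells of the conceptus, had 4 rises of 14 under both adjustments, in TKDP1 (0.88), PAG9 (0.63), IFNT2 (0.66) and TKDP4 (0.62). The adjusted p of the list was 0.3 with an estimated correlation. The trophoblast call was lost without SCNT animal 4 (median 0.07), AI animal 3 (0.165), CJ animal 1 (0.168), CJ animal 3 (0.166) or CJ animal 5 (0.161). Without SCNT animal 4, IFNT2 was 0.27 and PAG9 0.36, neither past the threshold, and TKDP1 was 0.50 without SCNT animal 1.

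Genes of the matrix, stromal and muscle lists fell in SCNT against CJ animals, list calls that were all lost with an estimated correlation (adjusted p = 0.0903 to 0.258 with an estimated correlation). Of the 9 stromal markers 7 are in the collagen or matrix list too, so these calls are partly of the same genes. Of 9 stromal fibroblast markers 7 fell (8 adjusted over the list alone; median -1.48, camera adjusted p = 8.92e-06, adjusted p = 0.16 with an estimated correlation). COL6A3 (-3.12 ± 0.35), COL1A2 (-3.04 ± 0.36), COL1A1 (-2.86 ± 0.34) and COL3A1 (-2.85 ± 0.37) led the collagens. Of these, 10 of 29 fell and 1 rose under both adjustments (median -0.12, or -0.19 without SCNT animal 4; adjusted p = 0.3 with an estimated correlation). Extracellular matrix and adhesion genes had 18 falls and 3 rises of 28 (21 and 3 adjusted over the list alone). TNC was at -2.39, TIMP1 at -1.65 and, the other way, the protease inhibitor TIMP2 at 1.68 (adjusted p = 0.258 with an estimated correlation). Smooth muscle markers had 6 falls of 10 (7 adjusted over the list alone), with ACTG2 at -2.67 and TAGLN at -2.28 (adjusted p = 0.0903 with an estimated correlation). Proteasome genes had 18 falls of 32 and 2 rises (20 and 4 adjusted over the list alone). PSMB5 was at -0.85 and, rising, the immunoproteasome subunits PSMB8 (0.55) and PSMB10 (0.63) (adjusted p = 0.138 with an estimated correlation). Cholesterol synthesis genes had 5 falls of 8 (6 adjusted over the list alone), with SQLE at -0.88 (adjusted p = 0.121 with an estimated correlation).

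Genes of oxidative phosphorylation, the mitochondrial ATP-producing chain, had 21 rises and 4 falls of 73 in SCNT against CJ animals (24 and 6 adjusted over the list alone; median 0.05, adjusted p = 0.348 with an estimated correlation). CYC1 was at 0.76. The median of the list was 0.10 without SCNT animal 4. Cytosolic ribosomal proteins had 21 falls and 4 rises of 66 (26 and 5 adjusted over the list alone; median -0.08, adjusted p = 0.322 with an estimated correlation). This call was lost without CJ animal 1 (-0.074), CJ animal 4 (-0.103), CJ animal 5 (-0.085) or SCNT animal 5 (-0.076). The lists below did not pass camera. Glycolysis genes had 8 falls and 3 rises, uterine secreted proteins 7 rises and 3 falls, chaperones and stress genes 7 rises and 6 falls, and nutrient transporters 4 rises and 3 falls. Endothelial markers had 4 rises and 1 fall, chemokines and cytokines 3 rises and 4 falls, prostaglandin genes 3 rises and 1 fall, and growth factors and vascular genes 3 rises and 1 fall. Steroid and oxytocin receptors had 2 rises and 3 falls, Wnt signalling genes 2 rises and 3 falls, IGF system genes 1 rise and 2 falls, and proliferation genes 0 rises and 4 falls. T and NK cell markers had 1 rise, and macrophage and B cell markers 0. Adjusted over the list alone, these counts moved by 2 at most.

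AI animals differed from CJ animals largely in the same groups. RSAD2 rose 11.2-fold (3.48 ± 0.68, 4 AI and 5 CJ animals, limma adjusted p = 0.00125, 7 of 10 arrays) and ISG15 7.46-fold (2.90 ± 0.62, adjusted p = 0.00252, 7 of 10 arrays). OXTR fell 6.56-fold (-2.71 ± 0.33, adjusted p = 1.13e-05) and SNAI2 5.61-fold (-2.49 ± 0.15, adjusted p = 1.84e-09), both on 10 of 10 arrays. NUPR1, a stress-response gene, rose by 1.84 ± 0.24, AGRN, a basement membrane proteoglycan, by 1.42 ± 0.17, and PTGDS, a prostaglandin D synthase, by 1.5 ± 0.19 (adjusted p = 2.14e-05). GADD45G (-2.36), PYCR1, an enzyme of proline synthesis (-1.85 ± 0.14, adjusted p = 3.2e-08), and IGFBP6, which binds insulin-like growth factors (-1.52), fell, as did PGR (-0.52 ± 0.13, adjusted p = 0.00617). In all, 957 probes were higher and 1117 lower (15.0% of those tested, 687 and 896 named genes), 202 of them by more than 1 on the log2 scale. The total of 2074 was 1286 without AI animal 2, 1335 without CJ animal 2, 1322 without CJ animal 4 and 1312 without CJ animal 5. ESR1 (-0.14), PTGS2 (0.01, its other probe -0.16) and SERPINA14 (-0.16) did not pass the test.

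AI animal 3 stood apart from the other AI animals. The median of the interferon-stimulated genes against CJ was 1.77, 2.08 and 1.39 in AI animals 1, 2 and 4 and -0.09 in AI animal 3. Without this animal, RSAD2 was 5.58, ISG15 4.61, MX1 4.50 (2.68 with it), COL1A1 -2.79 (-1.76), COL6A3 -2.91 (-1.85) and COL1A2 -3.25 (-2.09) against CJ, and the interferon list 1.49.

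**Figure D1:**
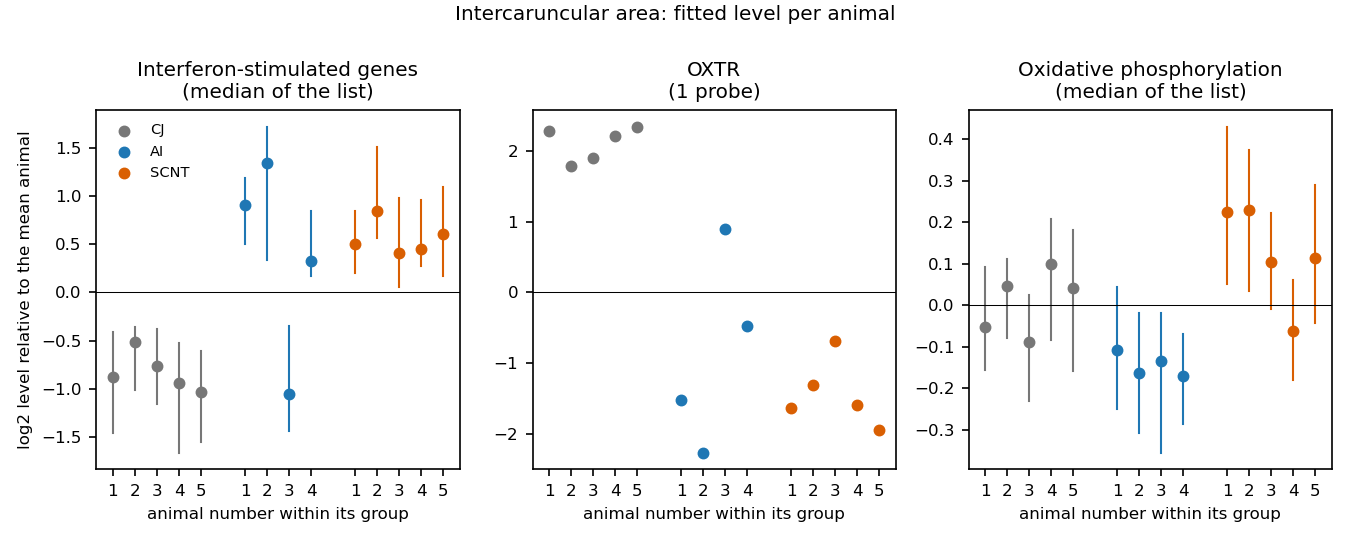
Level of the interferon-stimulated genes (median over 33 genes, log2), OXTR (log2) and the oxidative phosphorylation genes (median over 73 genes, log2) in each CJ, AI and SCNT animal of the intercaruncular area, each point 1 animal with quartiles over genes as lines for the lists. For the interferon-stimulated genes AI animal 3 lies at -1.05, beside the CJ animals (-1.03 to -0.52), and the SCNT animals lie between 0.40 and 0.85.

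Complement genes rose in AI against CJ animals, 8 of 16 with 0 falls (9 and 0 adjusted over the list alone). C1QC was at 1.19 ± 0.15 and C4A at 1.13 ± 0.15, and the call held with an estimated correlation (adjusted p = 0.00825). Epithelial markers, with 3 rises of 11 (6 adjusted over the list alone; CLDN3 0.98 ± 0.17), kept theirs too (adjusted p = 0.0408 with an estimated correlation). Of the interferon-stimulated genes 28 of 33 rose and 0 fell (29 and 0 adjusted over the list alone; median 0.85, camera adjusted p = 5.02e-13, adjusted p = 0.17 with an estimated correlation). MHC class II presentation had 5 rises of 8 under both adjustments, with CD74 at 1.19 and BOLA-DRA at 1.13 ± 0.11 (adjusted p = 0.0557 with an estimated correlation). Class I had 7 rises and 2 falls of 14 (10 and 2 adjusted over the list alone; adjusted p = 0.196 with an estimated correlation). The falls were again PDIA3 (-0.67) and CALR (-0.64). Proteasome genes had 19 falls and 3 rises of 32 (23 and 3 adjusted over the list alone). PSMD8 was at -0.75 ± 0.07, and the rises were in the immunoproteasome subunits PSMB8, PSMB9 and PSMB10 (adjusted p = 0.0557 with an estimated correlation). Cholesterol synthesis genes had 5 falls of 8 under both adjustments, with SQLE at -0.92 and FDPS at -0.78 (adjusted p = 0.0804 with an estimated correlation).

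In contrast to SCNT, oxidative phosphorylation genes had 21 falls and 2 rises of 73 in AI against CJ animals (26 and 3 adjusted over the list alone; median -0.13, camera adjusted p = 4.82e-05, adjusted p = 0.281 with an estimated correlation). NDUFA5 and COX7A2 were both at -0.67. Glycolysis genes had 8 falls and 1 rise of 16 (9 and 1 adjusted over the list alone; median -0.34, adjusted p = 0.293 with an estimated correlation). TPI1 was at -0.73, and the median of the list was -0.58 without AI animal 3. Smooth muscle markers had 3 falls of 10 (5 adjusted over the list alone; ACTG2 -2.12 ± 0.26; adjusted p = 0.143 with an estimated correlation). Stromal markers had 4 falls of 9 (5 adjusted over the list alone; median -0.67, adjusted p = 0.395 with an estimated correlation). Their median was -1.39 without AI animal 3, and the call was lost without CJ animal 2 (-0.575). Extracellular matrix genes had 9 falls and 1 rise of 28 (10 and 1 adjusted over the list alone; median -0.29, adjusted p = 0.559 with an estimated correlation), with POSTN at -1.02 and TIMP1 at -1.10. The matrix call was lost without AI animal 1 (-0.20), AI animal 2 (-0.162), AI animal 4 (-0.299), CJ animal 1 (-0.20) or CJ animal 2 (-0.189), and the median was -0.64 without AI animal 3 and -0.48 without CJ animal 3. Collagens did not pass camera here (7 falls and 3 rises, 8 and 3 adjusted over the list alone), nor did ribosomal proteins (10 falls and 9 rises, 11 and 9 adjusted over the list alone).

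Of the probes called in AI against CJ, 1543 (74.4%) were called in the same direction in SCNT against CJ, 695 higher and 848 lower, and 3 in the opposite direction. Independent lists of these sizes would share 225.3 in the same and 223.9 in the opposite direction. Because both comparisons use the same CJ animals, the overlap was also counted with the CJ animals split between them. Each comparison then used only the arrays of its part of the CJ animals, so fewer probes could be called than in the full fit. The shared calls had a median of 154.5 (0 to 704 over 20 splits), which cannot be set beside 1543 or 225.3. Simulated data without effects gave 0, which decides nothing because almost no probe is called in such data. The differences correlated across probes with r = 0.839 (probes are not independent replicates), against 0.179 in the simulations and a median of 0.707 with split CJ animals (0.31 to 0.819). Their covariance was 0.0951 against a simulated 0.00303, a difference of 0.0921. With 1 animal left out, 884 to 2310 calls were shared. The number was 1004 without AI animal 2, 1023, 884 and 992 without CJ animals 2, 4 and 5, and the highest number without AI animal 3.

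The comparison of SCNT with AI in the intercaruncular area asked how the tissue of these 2 groups differed, and it runs through the CJ animals. PLET1, LY6G6C and FABP3 were the most raised genes in SCNT animals. PLET1 was higher by 3.65 ± 0.49 (SE, 5 SCNT and 4 AI animals, limma adjusted p = 0.000576, 12.5-fold), LY6G6C by 2.74 ± 0.34 (adjusted p = 0.000576, 6.67-fold) and FABP3 by 2.98 ± 0.54 (adjusted p = 0.0109, 7.89-fold). UQCR11, a subunit of mitochondrial complex III (0.87 ± 0.12, adjusted p = 0.000576), ALAS1, the first enzyme of haem synthesis (0.86 ± 0.11, adjusted p = 0.000576), and ATP5MC3, a subunit of ATP synthase (0.78 ± 0.11, adjusted p = 0.000624), rose as well. These genes except FABP3 kept their call in each of the 14 fits that left out 1 animal, PLET1 at 3.32 to 4.04 and LY6G6C at 2.26 to 3.07.

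Among the other rises in SCNT against AI animals, CA2, a carbonic anhydrase, was at 1.65 ± 0.30 (adjusted p = 0.0106) and SLC15A1, a peptide transporter, at 1.41 ± 0.27 (adjusted p = 0.022). Others were FBP1, an enzyme of gluconeogenesis (1.28 ± 0.26, adjusted p = 0.0362), GJB2, a gap junction protein (1.20 ± 0.20, adjusted p = 0.00569), RAB3B, a vesicle GTPase (1.03 ± 0.16), SULT1A1, a sulfotransferase (0.99 ± 0.20), and FASN, fatty acid synthase (0.90 ± 0.16). In GJB2 and FASN 1 other probe each differed. The falls were PTGDS (-1.14 ± 0.24, adjusted p = 0.0449), COL7A1, the collagen of anchoring fibrils (-0.70 ± 0.15, adjusted p = 0.0387), LTBP3, which binds latent TGF-beta (-0.61 ± 0.11, adjusted p = 0.0106), and the ribosomal protein RPS3A (-0.55 ± 0.12, adjusted p = 0.0431). Against CJ, PTGDS was 1.5 ± 0.19 in AI and 0.36 in SCNT animals (adjusted p = 0.201), so its fall lay against the AI rise. PGR (-0.65 ± 0.16, adjusted p = 0.102), ISG15 (1.75 ± 0.78, adjusted p = 0.6), OXTR (-0.83 ± 0.41, adjusted p = 0.679) and ESR1 (-0.17 ± 0.19) did not pass the test.

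In all, 35 probes (28 named genes) were higher and 4 lower in SCNT than in AI animals. The count moved when single animals were left out, which also drops their arrays and can lose calls through lower precision alone. It was 8 without AI animal 3, 25 without AI animal 4, 23, 24, 8, 13 and 21 without CJ animals 1 to 5, and 22, 17 and 18 without SCNT animals 1, 2 and 5. Without AI animal 3 the 8 called probes included 7 of the 39, with PLET1 at 3.50, LY6G6C at 2.26, UQCR11 at 0.77, ALAS1 at 0.91 and ATP5MC3 at 0.85. FABP3 (2.26, adjusted p = 0.164), CA2 (1.71, adjusted p = 0.156) and COL7A1 (-0.50, adjusted p = 0.404) passed no longer. Of the 14 fits without 1 animal, UQCRC1 kept its call in 12, and COX8A, GJB2 and RAB3B kept their call in 11, FASN in 10, LTBP3 in 8, FABP3 and CA2 in 7, FBP1 in 6, SLC15A1 and SULT1A1 in 5, COL7A1 in 3, and PTGDS and RPS3A in 2.

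**Figure D2:**
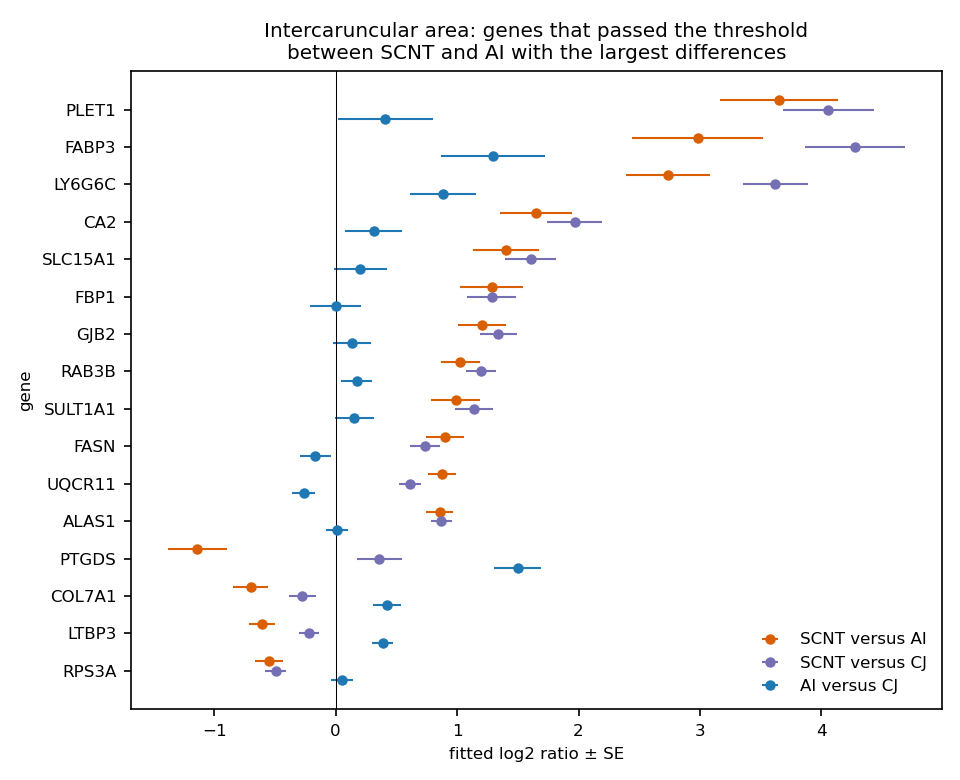
Differences (log2, points, with SE as bars) of the 16 genes with the largest rises and falls in SCNT against AI animals, beside the same genes in SCNT and AI against CJ, intercaruncular area. PLET1 was 4.06 in SCNT and 0.41 in AI against CJ, and PTGDS 0.36 in SCNT and 1.5 in AI.

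Oxidative phosphorylation was the list that set SCNT apart from AI most firmly. Of its 73 genes 65 lay higher and 8 rose past the threshold, with 0 falls (36 and 0 adjusted over the list alone; median 0.30, camera adjusted p = 1.83e-33). The call held with an estimated correlation (adjusted p = 0.00822) and in each fit without 1 animal (medians 0.24 to 0.36). COX8A (0.68 ± 0.11, adjusted p = 0.00569) and UQCRC1 (0.53 ± 0.09, adjusted p = 0.00433) were among the rises. Cytosolic ribosomal proteins were lower, with RPS3A the 1 fall (3 adjusted over the list alone; median -0.12, camera adjusted p = 2.28e-05, adjusted p = 0.179 with an estimated correlation; median -0.063 without AI animal 3). Glycolysis genes had 0 rises and 0 falls (4 and 1 adjusted over the list alone; median 0.17, camera adjusted p = 0.00972, adjusted p = 0.426 with an estimated correlation). SLC2A1 was at 1.23 ± 0.31 (adjusted p = 0.13). The glycolysis call was lost without AI animal 2 (0.04), AI animal 4 (0.10), CJ animal 2 (0.09) or SCNT animal 1 (0.095), and the median was 0.39 without AI animal 3.

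Interferon-stimulated genes were higher in SCNT than in AI animals as a list, but 0 of 33 passed the test singly (0 adjusted over the list alone; median 0.35, camera adjusted p = 1.95e-07, adjusted p = 0.349 with an estimated correlation). RSAD2 was at 1.96 ± 0.86 (adjusted p = 0.592). That call rested on AI animal 3, without which the median was -0.13. It was 0.55 without AI animal 1, 0.62 without AI animal 2 and 0.70 without CJ animal 2. Stromal markers (median -0.88, 0 falls, 2 adjusted over the list alone, camera adjusted p = 9.93e-06), matrix genes (-0.43, 0 under both adjustments, 1.43e-05), collagens (-0.14, 1 fall, 5 adjusted over the list alone, 0.000702) and smooth muscle markers (-0.33, 0 under both adjustments, 0.0278) were lower. All of these list calls were lost with an estimated correlation (adjusted p = 0.347 for each of the lists). They too were lost without AI animal 3 (stromal -0.06, matrix -0.05, collagens -0.021, smooth muscle -0.004). The smooth muscle call was also lost without CJ animal 3 (-0.253), SCNT animal 1 (-0.237) or SCNT animal 2 (-0.368). The collagen median was -0.213 without AI animal 2, -0.082 without CJ animal 3 and -0.07 without SCNT animal 5.

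**Figure D3:**
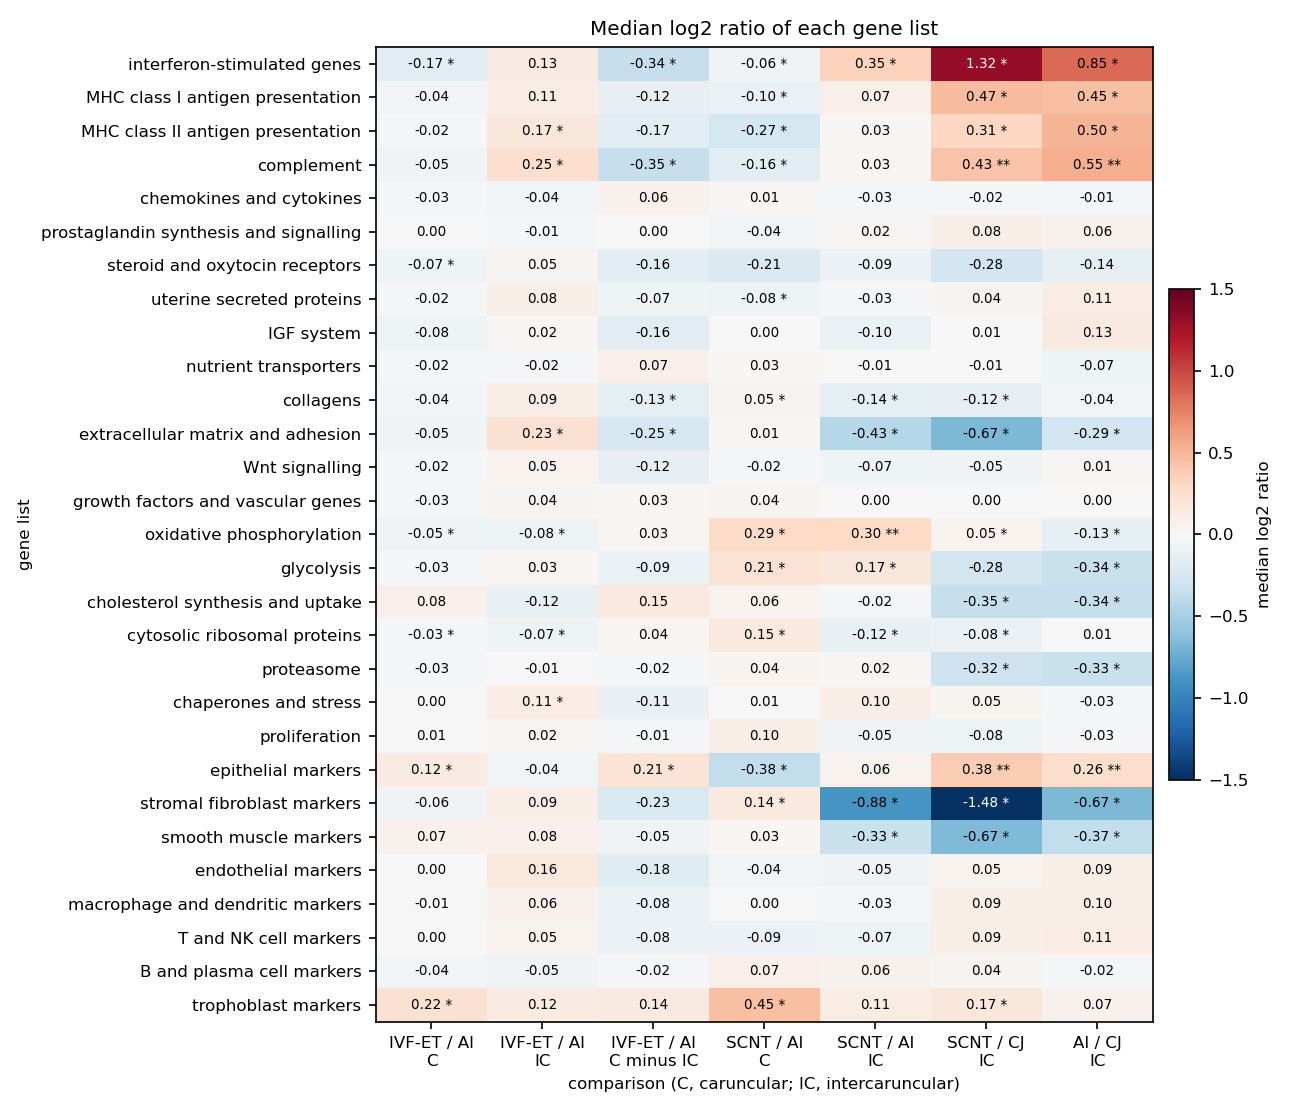
Median log2 difference of 29 gene lists (rows) in 7 comparisons (columns), as colour and number; 1 star marks lists past the threshold with camera, and 2 stars those that also pass with an estimated correlation. Oxidative phosphorylation had a median of 0.29 in SCNT against AI in the caruncular area and 0.30 in the intercaruncular area, and passed with an estimated correlation only in the latter.

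The same comparison in the caruncular area, where the placenta attaches, rested on pooled RNA. Antigen presentation and epithelial genes lay lower and mitochondrial and trophoblast genes higher in the SCNT pools, although no single probe passed the test. As lists these calls were all lost with an estimated correlation (adjusted p = 0.907 with an estimated correlation for each), and the median of the trophoblast list was raised in only 1 of the 2 pairs of pools (1.25 and 0.03). TKDP1, PAG2 and TKDP4 of that list were higher in both pairs, and PTI was lower in both. BOLA-DRB3, an MHC class II chain, was at -1.05 ± 0.08 (SE, 2 pairs of pools, limma adjusted p = 0.0753, lower on 4 of 4 arrays), BOLA-NC1, a non-classical MHC class I gene, at -1.10 ± 0.10 (adjusted p = 0.0753, with 1 of 2 other probes differing), and CD74, the class II invariant chain, at -1.27 ± 0.17 (adjusted p = 0.127). PTI, a trypsin inhibitor, was at -0.91 ± 0.08 (adjusted p = 0.0753) and UQCR11 at 0.80 ± 0.08 (adjusted p = 0.0997). TKDP1 and PAG2, secreted products of the ruminant trophoblast, were at 2.24 ± 0.34 (adjusted p = 0.127) and 1.93 ± 0.39 (adjusted p = 0.19), with TKDP1 at 3 in 1 pair of pools and 1.48 in the other. In all, limma called 0 probes, with 1744 at an unadjusted p under 0.05 (872 in each direction). With each array centred on its median 16 probes passed. With the 4 arrays taken as separate values 257 did, but this counts dye-swapped repeats of the same pools as replicates. The pairs of pools correlated with r = 0.365 across probes, and how many animals a pool held is not given in the sources used here.

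Oxidative phosphorylation genes lay higher in the SCNT pools as well, 68 of 73, with 0 past the threshold (45 rises and 1 fall adjusted over the list alone; median 0.29, camera adjusted p = 1.15e-23, adjusted p = 0.907 with an estimated correlation), at 0.29 in 1 pair of pools and 0.32 in the other. Epithelial markers lay lower, 11 of 11, with 0 past the threshold (7 falls adjusted over the list alone; median -0.38, camera adjusted p = 7.85e-07, adjusted p = 0.907 with an estimated correlation). ESRP1, an epithelial splicing regulator, was at -0.52 and the mucin MUC1 at -0.79. MHC class II presentation (-0.27, 4 falls adjusted over the list alone), class I (-0.10, 3 falls), complement (-0.16, 1 fall), interferon-stimulated genes (-0.06, 3 falls, IFI6 -0.84) and uterine secreted proteins (-0.08, 1 rise and 2 falls) lay lower. Glycolysis genes (0.21, 0 adjusted over the list alone), ribosomal proteins (0.15, 0), collagens (0.05, 4 rises, COL1A2 0.78), stromal markers (0.14, 2 rises) and trophoblast markers (0.45, 4 rises and 1 fall) lay higher. None of these 12 calls held with an estimated correlation (adjusted p = 0.907 to 0.92 with an estimated correlation), and 0 members of any list passed over all probes. ISG15 was at 0.00 ± 0.09 and OXTR at -0.26 ± 0.15.

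The 35 probes higher in SCNT than AI in the intercaruncular area were all higher in the caruncular SCNT pools too (35 of 35, median 0.48), a comparison chosen after these values were seen. Of the 4 lower probes 3 were lower there (median -0.064). In IVF-ET against AI, 4 of the 35 were higher in the caruncular (median -0.143) and 13 in the intercaruncular area (median -0.061). Whether the pools hold RNA of the same animals as the intercaruncular arrays is not given in the sources used here, so these are not known to be independent animals. FBP1 was at 1.13 ± 0.11 there (adjusted p = 0.0907), LY6G6C at 0.98 ± 0.14 (adjusted p = 0.127), FABP3 at 0.96 and PLET1 at 0.82, none past the threshold. Over all 13824 probes the SCNT differences of the areas correlated weakly (r = 0.175 across probes), and 53.8% had the same sign. The value was 0.095 without AI animal 2 and 0.344 without AI animal 3. The correlation with the IVF-ET differences was -0.051 in the caruncular and -0.073 in the intercaruncular area, and its sign turned without some single animals (-0.095 to 0.049 and -0.159 to 0.009).

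IVF-ET against AI in the caruncular area asked what embryo transfer after fertilisation in vitro changed, and few genes passed the test. ATP5F1C, a subunit of ATP synthase, fell 1.43-fold in IVF-ET animals (-0.52 ± 0.07, SE, 5 animals per group, limma adjusted p = 0.0232, lower on 10 of 10 arrays), and TGIF1, a repressor of TGF-beta signalling, fell 1.26-fold (-0.33 ± 0.04, adjusted p = 0.0232, 8 of 10 arrays). Genes of the conceptus had the largest values without passing the test, PRP1, a prolactin-related hormone, at 1.22 ± 0.31 (adjusted p = 0.361) and PAG9, a pregnancy-associated glycoprotein, at 0.93 ± 0.22 (adjusted p = 0.334). In all, limma called 0 probes higher and 3 lower, the remaining one without a gene symbol of its own, and 1260 had an unadjusted p under 0.05. ATP5F1C and TGIF1 passed in none of the 10 fits without 1 animal (adjusted p = 0.0514 or more), and the count was 2 without AI animal 5, 1 without IVF-ET animal 5 and 0 without any of the other 8 animals. Scaling the arrays to a common median absolute deviation ended both calls (adjusted p = 0.102 and 0.277), and a fit with no dye term that of TGIF1 (adjusted p = 0.431).

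Interferon-stimulated genes lay lower in caruncular tissue of IVF-ET than of AI animals, 30 of 33 below 0 with 0 past the threshold (3 falls adjusted over the list alone; median -0.17, camera adjusted p = 7.6e-07, adjusted p = 0.623 with an estimated correlation). RSAD2 was at -0.58 ± 0.15, IFI6 at -0.42 ± 0.10 and ISG15 at -0.18 ± 0.14. The call stood in each fit without 1 animal, but the median was -0.075 without AI animal 1 and -0.103 without IVF-ET animal 4. Oxidative phosphorylation genes lay slightly lower, with 1 fall (2 rises and 3 falls adjusted over the list alone; median -0.05, adjusted p = 0.623 with an estimated correlation). This call was lost without AI animal 2 (-0.038). Steroid and oxytocin receptors (-0.07, 1 fall adjusted over the list alone, adjusted p = 0.462 with an estimated correlation) lost theirs without AI animal 1 (-0.051), AI animal 3 (-0.056) or IVF-ET animal 3 (-0.047). Epithelial markers lay higher (0.12, 0 adjusted over the list alone, KRT8 0.59 ± 0.20, adjusted p = 0.706 with an estimated correlation). Their call was lost without AI animal 1 (-0.003), IVF-ET animal 3 (-0.005) or IVF-ET animal 4 (0.092), with medians of 0.20 without AI animal 4 or IVF-ET animal 5. Trophoblast markers lay higher (0.22, 2 rises adjusted over the list alone, adjusted p = 0.623 with an estimated correlation) and ribosomal proteins lower (-0.03, 0, adjusted p = 0.744 with an estimated correlation), both kept in 5 of the 10 fits without 1 animal. The trophoblast call was lost without AI animal 1 (0.24) or 3 (0.14) or IVF-ET animal 1 (0.13), 2 (0.18) or 3 (0.24), the median being 0.34 without IVF-ET animal 5. The ribosomal call was lost without AI animal 1 (-0.02) or 5 (0.01) or IVF-ET animal 1 (-0.03), 3 (0.00) or 4 (-0.05). It stood with a larger median without AI animal 2 (-0.056) or 4 (-0.091) or IVF-ET animal 2 (-0.055) or 5 (-0.074). OXTR (-0.05 ± 0.09), PGR (-0.12 ± 0.08) and PTGS2 (0.00 ± 0.05, its other probe -0.28) did not pass the test.

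In the intercaruncular area, THBS1, a matrix protein that regulates adhesion and vessel growth, was the single gene past the threshold between IVF-ET and AI animals. It rose 1.74-fold (0.80 ± 0.11, SE, 5 animals per group, limma adjusted p = 0.0488, higher on 10 of 10 arrays). Other adhesion and matrix genes had values of the same sign without passing, TIMP3 at 0.51 ± 0.12 and ITGB1, an integrin chain, at 0.38 ± 0.09 (both adjusted p = 0.332). In all, limma called 1 probe higher and 0 lower, with 1285 at an unadjusted p under 0.05. THBS1 passed in none of the 10 fits without 1 animal (adjusted p = 0.0809 or more). It also passed no longer without the array of IVF-ET animal 5 whose interferon values did not add up around the loop (0.83, adjusted p = 0.083), or with arrays scaled to a common median absolute deviation (adjusted p = 0.0843).

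Extracellular matrix genes lay higher in intercaruncular tissue of IVF-ET animals, with THBS1 the 1 rise (4 adjusted over the list alone; median 0.23, camera adjusted p = 0.000101, adjusted p = 0.558 with an estimated correlation). The median was 0.08 without AI animal 4 and 0.126 without IVF-ET animal 3. Complement genes lay higher too (0.25, 3 rises and 1 fall adjusted over the list alone, camera adjusted p = 0.0101, adjusted p = 0.289 with an estimated correlation). SERPING1, the C1 inhibitor, was at 0.55 ± 0.19 and, the other way, C4A at -0.66 ± 0.16. MHC class II presentation (0.17, 1 rise adjusted over the list alone, adjusted p = 0.558 with an estimated correlation) lost its call without AI animal 2 (0.113), AI animal 4 (0.189) or IVF-ET animal 4 (0.152). Oxidative phosphorylation genes (-0.08) and ribosomal proteins (-0.07) lay lower, each with 0 members past the threshold under both adjustments (adjusted p = 0.558 with an estimated correlation for both). The oxidative phosphorylation call was lost without AI animal 4 (-0.033), the median being -0.12 without AI animal 3 of this loop, which is not that of the CJ arrays. The median of the ribosomal proteins was -0.134 without AI animal 4. Chaperones and stress genes lay higher (0.11, 0 adjusted over the list alone, adjusted p = 0.558 with an estimated correlation) and kept their call in 5 of the 10 fits, losing it without AI animal 2 (0.07), 3 (0.08) or 5 (0.12) or IVF-ET animal 1 (0.13) or 4 (0.07). Interferon-stimulated genes did not pass (median 0.13, camera adjusted p = 0.187), but their median was -0.021 to 0.288 over the 10 fits without 1 animal and passed in 2 of them. ISG15 was at 0.23 ± 0.54 and MX1 at 0.64 ± 0.58, and OXTR (0.11 ± 0.22) and PGR (0.11 ± 0.15) did not pass either.

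Whether the IVF-ET effect differed between the areas was tested directly. IGFBP2, which binds insulin-like growth factors, had the only difference past the threshold, with an effect lower by 1.01 ± 0.16 (log2) in the caruncular than in the intercaruncular area (-1.01, limma adjusted p = 0.025). Interferon-stimulated genes (median -0.34, camera adjusted p = 0.000841), matrix genes (-0.25, 0.000354), complement genes (-0.35, 0.00251) and collagens (-0.13, 0.0177) had lower effects in the caruncular area and epithelial markers a higher one (0.21, 0.0313). With an estimated correlation none of these calls held (adjusted p = 0.149 with an estimated correlation for complement and 0.541 for the others), and adjusted over the list alone 1 matrix gene fell and 0 members of the others passed. In all, limma called 0 probes higher and 1 lower, with 1070 at an unadjusted p under 0.05, and IGFBP2 kept its call in 6 of the 20 fits without 1 animal of 1 area. Without 1 of the 8 animals shared by the areas in both of them, it passed in none (adjusted p = 0.0782 or more). It also lost it with a common median absolute deviation (adjusted p = 0.233) and without the intercaruncular array at odds with its loop (-0.99, adjusted p = 0.103). The interferon call was lost without intercaruncular AI animal 3 (-0.218), its median being -0.17 without intercaruncular AI animal 2 or IVF-ET animal 4. It also rests on the intercaruncular loop, around which the interferon ratios did not add up (median sum -2.64). With the array at odds turned, the difference of ISG15 was 0.267, so the interferon difference between the areas stays in doubt. The matrix call was lost without intercaruncular AI animal 4 (-0.116), and the collagen and epithelial calls stood in 13 and 11 of the 20 fits. Over these fits the collagen median was -0.18 to -0.074 and the epithelial median 0.043 to 0.349. With a shared animal left out of both areas, the interferon call was lost without caruncular AI animal 1 (-0.104) or IVF-ET animal 4 (-0.134). The collagen call was lost in 3 of these 8 fits (-0.095, -0.041 and -0.054) and the epithelial call in 4 (0.067, 0.224, 0.199 and -0.019). Matrix and complement calls stood in all 8, the matrix median being -0.101 without caruncular AI animal 2, -0.167 without IVF-ET animal 3 and -0.152 without IVF-ET animal 5. Across 13816 probes the IVF-ET effects of the areas correlated with r = 0.193 (0.116 without caruncular IVF-ET animal 1 and 0.127 without caruncular IVF-ET animal 4).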

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

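The tests of failed and reversed arrays, dye bias and RNA of another animal, and the fits without or with a turned array, were chosen after the results were seen.

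AI animal 3 of the intercaruncular arrays lay with the CJ animals in the interferon-stimulated genes, with a median of -0.09 against CJ where the other 3 AI animals had 1.39 to 2.08. A fit of the 10 SCNT and CJ arrays alone called 3281 probes outside the interferon list. Over these, its difference from CJ had a slope of 0.161 on the SCNT difference, against 0.876 to 1.03 in the other AI animals. Some of its values had been seen when this test was written. With levels set against the other CJ animals, its slope was 0.271, and AI animals 1, 2 and 4 had 0.872, 1.04 and 0.721. CJ animals 1 to 5 had -0.19, 0.01, 0.373, -0.196 and 0.004, so it lay above all of them except CJ animal 3. RNA of a CJ animal in place of that of AI animal 3 (a mislabelled sample) would give a slope in this range and stays open. That explanation leaves OXTR (-1.19) and SNAI2 (-2.24) at odds, which were below CJ in this animal too, SNAI2 as far as in AI animal 4 (-2.24). Failed arrays are argued against by the correlation of its dye-swapped pair (r = 0.446 across probes, and 0.292 or more between any 2 of its 4 arrays in opposite dyes), and reversed arrays by interferon medians of -0.184 to 0.06 on these 4 arrays, since those of the other AI animals had 1.155 to 2.31 and would turn as far below 0. An AI animal without the response to a conceptus may also look like this, which was not tested.

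In the intercaruncular IVF-ET and AI arrays, the ratios of the interferon-stimulated genes did not add up to 0 around the loop, with a median sum of -2.64 against -0.06 in the caruncular loop. Dye bias of the probes is argued against by this difference of -2.59, since the same probes added up in the other loop. An array with its dyes recorded the wrong way round, or RNA of another animal on 1 of the 2 arrays that share IVF-ET animal 5, may account for it, and both stay open. Over the other probes these 2 arrays correlated at 0.338, where other neighbours had -0.338 to 0.036, but each lay in that range with its other neighbour, the array at odds (IVF-ET in Cy3, AI in Cy5, replicate 5) at -0.187 (mean r of 0.075) and the second at -0.127 (mean r of 0.105), where turned dyes would move both pairs of an array. These pairs exclude neither, since arrays that share no animal had a mean r of -0.1, and the median sum was 0.29 with the array at odds turned (RSAD2 1.20) and 1.18 with the second turned.

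Single arrays lay far from the others of their group in 12 of 238 groups, and chance marks about 1 in 20 groups (5%); the values are log2 differences of SCNT or AI from CJ, or of IVF-ET from AI. With SCNT in Cy3 and CJ in Cy5, PTGS2 was -1.432 on replicate 3 (others -0.07 to 0.13) and ESR1 1.035 on replicate 1 (others -0.69 to -0.40). With CJ in Cy3 and SCNT in Cy5, the interferon median was 0.70 on replicate 4 (others 1.41 to 1.59), the trophoblast median 0.522 on replicate 3 (others -0.06 to 0.01), PGR -0.219 on replicate 4 (others -1.32 to -1.04) and PTGS2 0.572 on replicate 2 (others 0.05 to 0.14). With AI in Cy3 and CJ in Cy5, ACTG2 was -0.992 on replicate 4 (others -2.52 to -2.27) and ESR1 -0.952 on replicate 5 (others -0.18 to 0.13). With AI in Cy3 and IVF-ET in Cy5 of the intercaruncular area, PTGS2 was -0.973 and OXTR 2.591 on replicate 1 (others -0.10 to 0.21 and -0.23 to 0.48). With IVF-ET in Cy3 and AI in Cy5, ISG15 was 3.353 on replicate 5 (others -0.20 to 0.68) and PTGS2 1.107 on replicate 4 (others -0.26 to 0.03).

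Between the areas, a test of the difference marked the IVF-ET effects on IGFBP2 (-1.014) and on interferon-stimulated genes (median -0.343), complement genes (-0.351), collagens (-0.13), matrix genes (-0.252) and epithelial markers (0.206). None of the list calls held with an estimated correlation (adjusted p = 0.149 for complement and 0.541 for the others). The interferon value also rests on the intercaruncular loop whose interferon ratios did not add up. IGFBP2 kept its call in 6 of the 20 fits without 1 animal of 1 area and in none without a shared animal in both areas, and 8 of 100 splits of the animals gave as many probes (real 1, highest other 18), so chance cannot be excluded.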

How the results depend on the processing

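All fits without or with a turned array, with a block or with an animal left out of both areas, and the lists, agreements and overlaps with 1 animal left out, were chosen after seeing the data. Replicate numbers only name arrays, so they pair nothing, but 5 IVF-ET and 3 AI animals are in both areas. With each animal as a replicate block over both areas, the part of the correlation common to its areas was estimated at 0, so the difference between areas kept its 1 probe (IGFBP2 -1.014, adjusted p = 0.025) and 5 lists. Of the values of single genes under the alternatives, 8587 kept their direction and side of the threshold, 296 were no longer past it, 54 newly past it and 105 reversed, none of the reversed genes being past the threshold before; of the counts and correlations, 270 stayed within 1.5-fold or the spread and 126 moved. Medians of called lists turned too: IVF-ET versus AI, caruncular, epithelial markers to -0.003 and -0.005 without AI animal 1 or IVF-ET animal 3, and ribosomal proteins to 0.007 and 0.001 without AI animal 5 or IVF-ET animal 3; SCNT versus AI, intercaruncular, interferon-stimulated genes to -0.133 without AI animal 3; and for the difference between areas, epithelial markers to -0.019 without IVF-ET animal 3 in both areas and collagens to 0.012 with the neighbouring array turned. The cause was not tested unless the alternative itself names it. Signal over background was not analysed here.

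Counts of probes moved as follows. IVF-ET versus AI, caruncular, had 0 with a common median absolute deviation or at 0.01, and 0 to 2 without 1 animal. IVF-ET versus AI, intercaruncular, had 2 with no dye term or robust moderation, 0 with a common deviation, at 0.01, and without or turning either array of IVF-ET animal 5, and 0 without any 1 animal. The difference between areas had 0 with a common deviation, at 0.01, without or turning the array at odds and turning its neighbour, and 0 to 1 without 1 animal (0 for each shared animal left out of both areas). SCNT versus AI, caruncular, had 16 with median centring and 257 with the 4 arrays taken separately, which counts dye-swapped repeats of the same pools as replicates. At 0.01, SCNT versus AI, intercaruncular, had 16, SCNT versus CJ 1927, AI versus CJ 1219 and their overlap 889. Without 1 animal SCNT versus AI, intercaruncular, had 8 to 53, AI versus CJ 1286 to 2826 and the overlap 884 to 2310. Taking AI animal 3 as 2 animals gave 44, 3169 and 2320 calls for SCNT versus AI, SCNT versus CJ and AI versus CJ.

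Lists past the threshold with an estimated correlation, in the order of the comparisons above, numbered 0, 0, 0, 0, 1, 2 and 2, and with fry 1, 0, 1, 0, 2, 19 and 16. Without the array at odds 10 lists passed in IVF-ET versus AI, intercaruncular. Without 1 animal the numbers were 2 to 9, 4 to 11, 3 to 10 and, for SCNT versus AI, intercaruncular, 3 to 10. Without 1 animal, the agreement of IVF-ET effects between areas was 0.116 to 0.258, the agreement of SCNT effects between areas 0.095 to 0.344, and the agreement of IVF-ET and SCNT effects in 1 area -0.095 to 0.049, caruncular, and -0.159 to 0.009, intercaruncular. With all animals, the agreement of IVF-ET effects was 0.896 over the probes past the threshold. These are 3 probes called in the caruncular and 1 in the intercaruncular area, picked by the same effects, so this value cannot show agreement.

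Genes not past the threshold reversed. In IVF-ET versus AI, caruncular, PTGS2 was -0.009 with a common deviation, -0.141 as the mean of its probes and -0.016 to 0.033 without 1 animal, and OXTR -0.099 to 0.047. In the intercaruncular area, without and turning the array at odds, ISG15 was -0.091 and -0.443; turning it, MX2 was -0.023 and MX1 -0.19, and without it PTGS2 was 0.001. Without and turning its neighbour, PGR was -0.023 and -0.184, PTGS2 0.087 and 0.182, and OXTR -0.133 and -0.405. Without 1 animal, ISG15 was -0.245 to 0.873, PGR -0.073 to 0.213, MX2 -0.254 to 0.693, PTGS2 -0.18 to 0.138, OXTR -0.147 to 0.234, SERPINA14 -0.136 to 1.034 and ESR1 -0.231 to 0.069. For the difference between areas, turning the array at odds gave ISG15 0.267 and SERPINA14 0.372 (0.114 without it, 0.322 with a common deviation); without and turning the neighbour, PTGS2 was -0.082 and -0.18 and OXTR 0.09 and 0.358, and turning it PGR 0.06. Without 1 animal, ISG15 was -1.081 to 0.087, MX2 -0.991 to 0.053, PTGS2 -0.133 to 0.181, OXTR -0.29 to 0.108, SERPINA14 -0.494 to 0.788 and ESR1 -0.188 to 0.168. In SCNT versus AI, intercaruncular, without 1 animal, RSAD2 was -0.133 to 2.695, CNN1 -1.471 to 0.212, MYLK -0.6 to 0.125, MX2 -0.128 to 1.788, MX1 -0.444 to 1.879, OXTR -1.269 to 0.007, SERPINA14 -1.269 to 1.578 and PTGS2 -0.155 to 0.103 (0.501 as the mean of its probes). Against CJ, PTGS2 was 0.425 in SCNT and -0.076 in AI as the mean of its probes, -0.145 to 0.113 and -0.035 to 0.043 without 1 animal, and SERPINA14 -0.509 to 0.615 and -1.428 to 1.42.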

Other observations

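Lists of chaperones and stress genes (7 rises and 6 falls), nutrient transporters (4 and 3) and Wnt signalling genes (2 and 3) went both ways in SCNT against CJ animals in the intercaruncular area and did not pass camera, and some of their single members differed. HSPA5 and HSP90B1, chaperones of the endoplasmic reticulum, fell by 1.02 ± 0.09 (limma adjusted p = 8.28e-08) and 1.10 ± 0.11 (adjusted p = 9.24e-07) on 10 of 10 arrays, and in AI animals by 0.83 ± 0.09 and 0.99 ± 0.12. SOD2, the mitochondrial superoxide dismutase (1.48 ± 0.21), TXNIP, which binds thioredoxin (1.77 ± 0.26), and EPAS1, a hypoxia-inducible factor (1.81 ± 0.30), rose. While the glucose transporter SLC2A1 rose, the amino acid transporters SLC7A5 (-0.75 ± 0.14) and SLC1A5 (-0.71 ± 0.14) fell on 9 of 10 arrays, and lactate dehydrogenase LDHA (-1.29 ± 0.28) on 10 of 10. In the Wnt pathway the inhibitor DKK1 rose, and AXIN2, a target of the pathway (-0.97 ± 0.13), and DKK3 (-1.18 ± 0.21) fell. The cell cycle genes CCNB1 (-0.93 ± 0.14) and PCNA (-0.61 ± 0.11) fell too. Each of these genes kept its call against CJ in SCNT animals in all 14 fits without 1 animal.

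The tests of epithelium and short transcripts below, the splits of lists and the splits that move an animal in both areas were chosen after the results were seen. Oxidative phosphorylation genes lay higher in SCNT than AI in both areas (medians 0.29 and 0.30). The AI animal with a CJ-like interferon profile is argued against as the source in the intercaruncular area, since the median there was 0.288 without it. Short abundant transcripts favoured by RNA quality or labelling are argued against in that area alone, where the ribosomal proteins were at -0.116 (-0.063 without AI animal 3). In the caruncular pools the ribosomal proteins were higher (0.15, with 0.07 and 0.18 in the 2 pairs), so short transcripts stay open there. A different share of epithelium may contribute in the intercaruncular area, where the epithelial markers had a median of 0.057 over members of both signs, which decides nothing; in the caruncular pools they were lower (-0.38). An effect of cloning on the tissue stays open and untested. No array set SCNT against IVF-ET, so cloning cannot be told apart from other differences between SCNT and AI animals.

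Other splits of the animals, 100 per comparison with the real one included, tested the counts of called probes. For IVF-ET against AI, 3 splits gave as many in the caruncular area (real 3, highest other 10) and 1 in the intercaruncular area (real 1, highest other 0). Their shares were 0.036 and 0.03 adjusted over the 6 comparisons, but these cannot exclude chance. Only the real grouping sets IVF-ET against AI on all 10 arrays of a loop, so every other split was tested with less precision. The 2 counts also rest on few probes, as 0 to 2 and 0 passed without 1 animal. For the difference between the areas 8 splits gave as many with each area split on its own (real 1, highest other 18). With each animal moved in both of its areas 6 did (real 1, highest other 4), and 17 of all 196 such splits (highest other 17), so chance cannot be excluded. Splits with 10 and 18 calls, several times the real count, are what a structure of the animals besides the groups would give, which was not tested. For SCNT against AI in the intercaruncular area 2 splits gave as many (real 39, highest other 41), which cannot exclude chance either. Most other splits did not set each CJ animal equally often against both groups, so they were tested with less precision. For SCNT against CJ 1 did (real 2994, highest other 2889) and for AI against CJ 2 (real 2074, highest other 2312). In these 2 comparisons too, other splits set the groups against each other on fewer arrays, so the shares alone cannot exclude chance.

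For the medians of the called lists, all 126 splits of the animals were made, or 100 for the difference between the areas. The shares below are not adjusted. Except for SCNT against AI, the other splits set the groups against each other on fewer arrays than the real one. In SCNT against AI, most other splits did not set each CJ animal equally often against both groups. The medians of other splits could therefore spread more widely, and a large share does not show chance. Adjusted over the 29 lists, no share was under 0.05 (smallest 0.0767, and 0.345 for oxidative phosphorylation in SCNT against AI), but with a smallest possible share of 0.00794 a list could not pass alone. For oxidative phosphorylation in SCNT against AI in the intercaruncular area, 3 splits gave a median as large (real 0.297, highest other 0.329, share 0.0238). For the interferon-stimulated genes of IVF-ET against AI in the caruncular area 28 did (real -0.171, highest other 0.28, share 0.222), and chance cannot be excluded. Under 5% of the splits gave a median as large for 0 of 6 called lists of IVF-ET against AI in either area, 3 of 8 of SCNT against AI in the intercaruncular area, 10 of 14 of SCNT against CJ and 6 of 12 of AI against CJ. For the difference between the areas this held for 0 of 5 with each area split on its own, and with each animal moved in both areas for complement alone (5 of 196, real -0.351, highest other 0.409).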
